A study of Mus musculus with 9 samples.

How the data were processed

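RNA from cerebella of mice carrying SmoA1, which the labels call a medulloblastoma strain, was profiled on 9 arrays with 2 colours each. The animals were at postnatal day 20. According to the labels, 5 arrays carry Pycard wild-type and 4 carry Pycard knockout samples, labelled in Cy5. The other channel of every array, in Cy3, is the same reference, a pool of wild-type cerebella at postnatal day 16. No array has the dyes exchanged. Nothing states that each array is a separate animal, so p-values measure the spread between these samples, which may be technical.

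The values are the submitters' processed log ratios, 1 per array feature and array. Agilent Feature Extraction is named in the submitters' processing notes, and its version, background correction, dye normalization and filters are not given in the sources used here. The deposited table was taken as log2 of sample over reference. This base is read from the values, since each array holds between 20 and 280 values larger than 4.82, the most that log10 of a ratio of 16-bit signals can reach. The direction comes from the dyes per the labels, and Pycard is lower on the arrays labelled knockout. The table holds 45220 features and no missing cell. Array medians lie between 0 and 0.013, and the SD over features runs from 0.552 on knockout 1 to 1.12 on wild-type 4. Exact zeros make up 1.07% to 7.35% of an array, and 252 features are zero on every array. No signal intensity comes with the ratios, so dim, saturated and control spots were not separated from the rest. For arrays the number of arrays limits the precision.

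The platform's annotation lists a gene for 33709 features, of which 33653 have 1 symbol and 56 several. The other 11511 are unnamed here, and control spots, if present, are among them. Symbols were compared through gene identifiers with a RefSeq table of assembly GRCm38.p6, and 0 changed. That table was used only for names and for the order of genes along a chromosome. Features of 1 symbol were averaged (8343 genes have more than 1 feature), and every other feature was kept on its own. This gave 30654 values per array, 19087 of them for named genes.

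Knockout was compared with wild-type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 9 arrays without covariates, with Benjamini-Hochberg adjustment over the 30654 values and a threshold of adjusted p under 0.05. The intercept of the same fit gave the wild-type mean against the reference, with the same threshold and a mean of at least 1 either way. Gene lists, 35 in number with 744 genes of which 681 were measured, were tested by limma's camera with a preset correlation between genes of 0.01 and adjustment over the 35 lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean over the 126 ways to divide 9 arrays into 5 and 4. The smallest p that test can give is 0.00794. A list's difference is that of the mean over its genes per array, and its SE comes from the spread between arrays. Intervals are at 95%.

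The genes named in the text follow a rule. It takes Pycard; up to 12 named genes each way past the threshold with both groups separated, filled up by the smallest unadjusted p; in each called list, and in the lists on cell cycle, Hedgehog, granule neurons, inflammasome, microglia and p53, the 2 members with the smallest p and the 2 with the largest change; a fixed set and the 8 highest and 8 lowest genes against the reference with all 9 arrays on one side of 0; and sex-linked genes per array. Predicted and numbered transcripts were left out. The lists, this rule, the tests and the other settings tried were fixed before the data were examined. Those settings were blocks on replicate number and on title style, each style alone, each array left out, median centring, quantile normalization, a filter on SD, features tested singly, array weights, a trended robust prior, other thresholds, an Xist covariate, sex-linked genes left out, lists without Pycard and its neighbours, other list tests and an unmoderated two-sample test. Settings chosen after seeing the data were exact zeros taken as missing, a block on array sets, an Eif2s3y covariate, named genes alone and the set of 4 arrays alone.

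Replicate numbers 1 to 4 occur in both genotypes in the labels, which do not say what a number stands for. Deviations of same-numbered arrays from their group means correlated at 0.251, 0.214, 0.347 and 0.204 for the 4 pairs, all over 0.1. The numbers were therefore taken as a possible pairing of the samples, which is an assumption. The main fit leaves this pairing out, and a block on replicate number is given beside it. Knockout 2 correlated more with wild-type 1 (0.236) than with wild-type 2, and knockout 4 more with wild-type 5 than with wild-type 4. The values thus do not single out the numbered pairs. Average-linkage clustering of the same deviations, cut into 3, gave sets of arrays, and these are wild-type 1 and 2 with knockout 1 and 2, then wild-type 3 with knockout 3, and lastly wild-type 4 and 5 with knockout 4. In the last set knockout 4 correlated with wild-type 4 (0.204) and wild-type 5 (0.247), while those wild-type arrays were at -0.198 to each other. The clustering thus joined these wild-type arrays only through knockout 4. That set is also the 3 arrays whose titles end in a number, where the other 6 end in a letter. Comparisons within the number-titled arrays thus rest on 1 knockout array, knockout 4. No scan date or slide was used here. Correlations between arrays over genes ran from 0.235 to 0.758, so no array repeats another.

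The gene test was tested on simulated data of 30654 values per array with the groups of knockout against wild-type. It recovered 31 of 100 values changed by 1 on the log2 scale and 74 of 100 changed by 2, with 1 false call. In simulated lists for the same comparison, camera called 2 of 2 lists shifted by 0.5 and 0 of the unshifted ones. The simulated genes were drawn independently, whereas the estimated correlation in the real G2/M and mitosis list was 0.72. The simulation therefore cannot show how often camera calls unshifted lists of correlated genes. Figures were drawn with matplotlib 3.10.9.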

Results

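Gene expression was measured in cerebellum of SmoA1 mice, which express an activated form of Smoothened in granule neuron precursors and develop medulloblastoma, with or without Pycard. Pycard encodes ASC, the adaptor that links inflammasome sensors to caspase-1. The comparison asks how loss of ASC changes the cerebellum of a tumour-prone strain, sampled at postnatal day 20. Each value is the log2 ratio of 1 sample over a common pool of wild-type cerebella at postnatal day 16, from 5 wild-type and 4 knockout arrays.

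Pycard was lower on all 4 knockout arrays than on all 5 wild-type arrays. Its mean log2 ratio was 1.08 ± 0.26 (SD, n = 5) in wild-type and -2.39 ± 0.64 (SD, n = 4) in knockout, a difference of -3.47 (SE 0.292, 95% interval -4.14 to -2.81, limma adjusted p = 0.0131). The exact permutation p was 0.00794, the smallest that 126 splits can give. Of the 2 Pycard features, 1 fell by 4.62 and passed on its own (limma adjusted p = 0.000464). The other differed by -2.32 without passing (limma adjusted p = 0.925), and its groups did not overlap, with a highest knockout value of -0.054 on knockout 3 and a lowest wild-type value of 0.446. Whether either feature lies in the deleted part of the gene is not given in the sources used here.

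Besides Pycard, the values of Slx1b and Gdpd3 differed between the genotypes, those of Slx1b in 1 of its 2 features only. Slx1b, which encodes a subunit of a structure-specific DNA endonuclease, fell by 2.39 on the log2 scale (SE 0.117, limma adjusted p = 0.00056). Gdpd3, a glycerophosphodiester phosphodiesterase gene, rose by 2.54 (SE 0.217, limma adjusted p = 0.0131), from a wild-type mean of -1.31 to a knockout mean of 1.23. The Slx1b change came from 1 of its 2 features, which differed by -4.71 (limma adjusted p = 6.6e-06), while the other differed by -0.0691 (limma adjusted p = 0.968). The fall of 2.39 is the average of these features, so a fall of the Slx1b transcript was not shown. Gdpd3 has 1 feature. Unnamed feature 3412 was lower in knockout by -2.98 (SE 0.235, limma adjusted p = 0.0131) and unnamed feature 21783 higher by 1.29 (SE 0.117, limma adjusted p = 0.0169); both fall outside the naming rule and were singled out after their values were seen. These 5 of 30654 values, 2 higher and 3 lower, are all that passed, and 1656 had an unadjusted p under 0.05 where 1532.7 would by chance. With the replicate number as a block, limma called 0 values (1868 with an unadjusted p under 0.05), and adjusted p was 0.124 for Slx1b, 0.705 for Gdpd3, and 0.751 for Pycard and both unnamed features. The differences with the block were -2.44 (SE 0.0890) for Slx1b, 2.49 (SE 0.158) for Gdpd3, -3.41 (SE 0.354) for Pycard, -2.99 (SE 0.232) for feature 3412 and 1.27 (SE 0.109) for feature 21783. The block uses up degrees of freedom. With it the SE was smaller for Slx1b, Gdpd3 and both unnamed features and larger for Pycard. The lost calls therefore do not show that pairing removes the differences. Without the block, Slx1b passed with any 1 array left out, while Pycard and Gdpd3 passed only without wild-type 3 or without knockout 3, with the highest adjusted p at 0.0962 for Pycard (without knockout 2) and 0.0887 for Gdpd3 (without knockout 2).

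**Figure D1:**
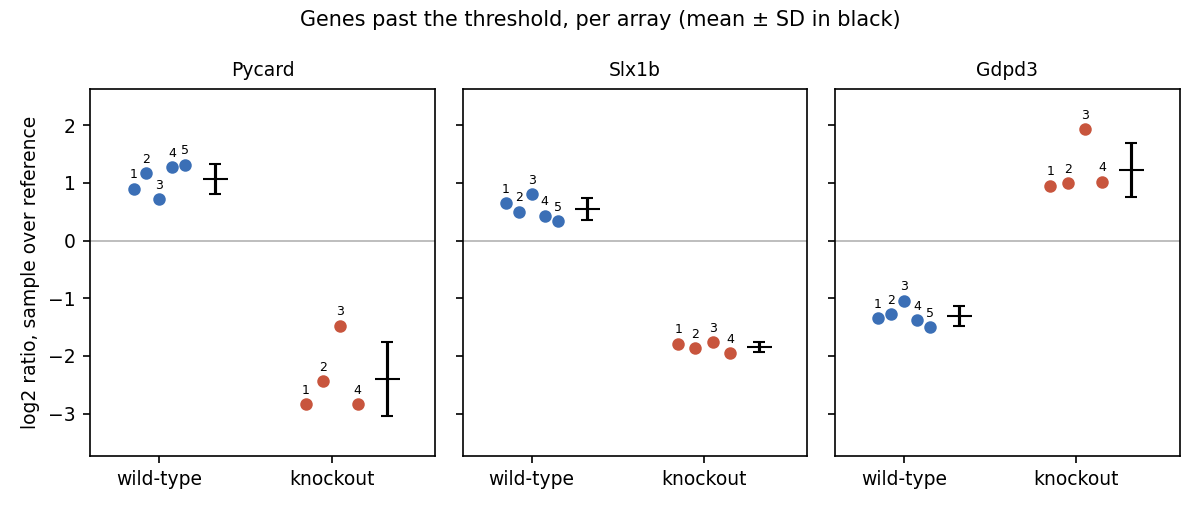
Log2 ratio over the reference (vertical axis) of Pycard, Slx1b and Gdpd3 on each array, by genotype. Pycard and Slx1b are averages of 2 features each, and only 1 of the 2 Slx1b features differed. Points are arrays with their replicate number and black bars are mean ± SD (n = 5 wild-type, n = 4 knockout). The groups do not overlap in any of the 3 genes, and Gdpd3 on knockout 3, at 1.93, lies above the other knockout arrays.

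No further gene passed the threshold, and those with the smallest p among genes with separated groups had limma adjusted p = 0.917. Higher in knockout in this sense were Tmem125 (difference 0.77), Msln (0.78), Wfdc18 (0.67), Nkain2 (0.56), Armc5 (0.46), Usp17lc (0.85), Bace2 (0.52), Gpr37l1 (0.44), Nkx6-2 (0.57), Mfap5 (0.74) and Dbndd2 (0.38). Nkx6-2 is a transcription factor of oligodendrocytes, but it lies 77 measured genes from Pycard on chromosome 7. Armc5 lies 5 measured genes from Pycard. Lower were Igf2bp3 (-0.77), Fignl1 (-1.15), Angptl1 (-1.01), Tigar (-0.77), Pou4f1 (-1.31), Gpnmb (-1.14), Retnlg (-0.77), Cenpv (-0.48), Dmrt1 (-0.60) and Prim1 (-0.86). Prim1 encodes the catalytic primase subunit and Pou4f1 a neuronal transcription factor. Groups were separated in 409 of 19087 named genes (2.14%), where chance gives 1.59%.

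Genes of cell division had lower mean ratios in knockout, and of the list tests only camera with the preset correlation called them. The G2/M and mitosis list had a mean log2 ratio of 2.87 ± 0.37 (SD, n = 5) in wild-type and 1.76 ± 0.77 (SD, n = 4) in knockout, a difference of -1.11 (SE 0.386), and all 32 measured members were lower. Among them were the kinesin Kif2c (-1.37), the mitotic kinases Plk1 (-1.19) and Aurkb (-1.63), and the centromere motor Cenpe (-1.65). None of the 32 passed over all genes, and 20 passed as lower adjusted over the list alone. Camera gave the list an adjusted p = 7.9e-25 with the preset correlation and adjusted p = 0.276 with an estimated correlation. Fry gave adjusted p = 0.149. The exact permutation p was 0.0159 (adjusted p = 0.167), and the list was lower in knockout in all 4 numbered pairs. Its mean was 0.74 on knockout 1, the lowest, and 2.16, 2.50 and 1.64 on knockout 2, 3 and 4. The difference was -0.83 within the letter-titled arrays and -1.58 within the number-titled ones. Within the 3 array sets it was -1.19, -0.11 and -1.58, the middle value being wild-type 3 against knockout 3.

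The G1/S and DNA replication list differed by -0.78 (SE 0.293), with all 32 members lower and 0 passing, adjusted over all genes or over the list alone. Mcm7 (-0.93) and Mcm6 (-1.36), subunits of the replicative helicase, Prim1 (-0.86) and the licensing factor Cdc6 (-1.21) were its leading members. Camera gave adjusted p = 2.9e-20, and adjusted p = 0.276 with an estimated correlation; the exact permutation p was 0.0238. The DNA damage response and repair list, many of whose members are also transcribed in cycling cells, differed by -0.45 (SE 0.168), with 25 of 26 members lower, among them Chek1 (-1.40), Fancd2 (-1.01), Brca2 (-0.72) and Fanci (-0.66). Its adjusted p was 1.7e-09, and adjusted p = 0.276 with an estimated correlation. All 35 cytosolic ribosomal protein genes were lower, by -0.31 on average (SE 0.133), including Rps9 (-0.51), Rplp0 (-0.54) and Rpl4 (-0.59). Here adjusted p was 1.6e-13, and adjusted p = 0.324 with an estimated correlation. After quantile normalization the ribosomal difference was -0.13 (SE 0.167). Cdc6 was at -0.75 without knockout 1 and Fancd2 at -0.54 without wild-type 4. Between wild-type 3 and knockout 3 alone these lists differed by -0.06 for G1/S, 0.02 for DNA damage and -0.01 for ribosomal proteins, so they differed little in that array set.

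Camera with the preset correlation also called lower in knockout Hedgehog pathway genes and markers of granule neuron progenitors, the cells in which SmoA1 acts. The Hedgehog list differed by -0.39 (SE 0.162), with 14 of 19 members lower, such as Mycn (-1.17), the chemokine receptor Cxcr4 (-1.21) and Sfrp1 (-1.21). Camera gave adjusted p = 0.000507, and adjusted p = 0.324 with an estimated correlation. Gli1 differed by -0.49 and Ccnd1 by -0.53. Granule neuron progenitor markers differed by -0.36 (SE 0.160), with 13 of 17 lower, including Atoh1 (-1.49), Barhl1 (-0.60), Nhlh1 (-0.79) and Insm1 (-0.89). Their adjusted p was 0.000507, and adjusted p = 0.341 with an estimated correlation, and without knockout 1 they differed by -0.21. Leaving out the same array put Sfrp1 at -0.71, Nhlh1 at -0.50 and Insm1 at -0.51. No member of either list passed over all genes or over the list alone. Within the array sets the Hedgehog list differed by -0.37, -0.14 and -0.51, and the progenitor list by -0.50, 0.03 and -0.39.

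Lists of markers of differentiated cerebellar cells were called higher in knockout with the preset correlation. Oligodendrocyte genes rose as a list by 0.37 (SE 0.0795), from -1.02 ± 0.14 (SD, n = 5) to -0.66 ± 0.08 (SD, n = 4), and 15 of 17 members were higher, including the myelin genes Opalin (0.68), Cldn11 (0.74) and Mal (0.38). Every knockout array lay above every wild-type array, with an exact permutation p = 0.00794 (adjusted p = 0.167). Camera gave adjusted p = 2.4e-09, and adjusted p = 0.257 with an estimated correlation, the smallest of the 35 lists. Within the array sets the difference was 0.35, 0.23 and 0.46, and after quantile normalization it was 0.21 (SE 0.139). Purkinje cell markers differed by 0.26 (SE 0.10), with Pvalb (0.68) and Pcp2 (0.54) leading and 13 of 16 higher (adjusted p = 0.000487, and adjusted p = 0.276 with an estimated correlation), and single features gave 0.16. Their differences within the array sets were 0.35, 0.0036 and 0.34, with knockout 3 at -0.63 beside wild-type 3 at -0.63. All 20 granule neuron maturation genes were higher, by 0.20 (SE 0.126), among them Calb2 (0.33), Gabra6 (0.39) and the synaptic vesicle gene Vamp2 (0.21), with adjusted p = 0.000802, and adjusted p = 0.458 with an estimated correlation. This difference was 0.13 after quantile normalization, 0.13 without wild-type 4, 0.14 without knockout 4 (call lost) and 0.029 within the letter-titled arrays (call lost). By array set it was 0.11, -0.14 and 0.55, and without knockout 4 Calb2 was at 0.21 and Gabra6 at 0.24. Interneuron markers differed by 0.18 (SE 0.136; Slc32a1 0.46, Kit 0.33, Slc6a5 0.48), with adjusted p = 0.0198, and adjusted p = 0.374 with an estimated correlation. Their call was lost after quantile normalization (0.10), without knockout 1 (0.14), knockout 2 (0.16), knockout 4 (0.13) or wild-type 3 (0.12), while without knockout 3 the difference was 0.31. It was 0.20, 0.10 and 0.29 within the array sets, and Slc6a5 was at 0.30 without knockout 1. Astrocyte and Bergmann glia markers differed by 0.14 (SE 0.0950), with Ntsr2 (0.41), Timp4 (0.37) and Gdf10 (0.81) higher and Fabp7 (-0.51), a marker of immature glia, lower. Their adjusted p was 0.0408, and adjusted p = 0.472 with an estimated correlation. The astrocyte call was lost after quantile normalization (0.027), without knockout 1 (0.13), knockout 3 (0.14), knockout 4 (0.12), wild-type 3 (0.11) or wild-type 4 (0.068), and within letter-titled arrays (0.047). Within the number-titled arrays, with knockout 4 as the only knockout array, the astrocyte difference was 0.30. By array set the astrocyte difference was -0.035, 0.21 and 0.30, and Fabp7 was at -0.80 without knockout 3. Endothelial and pericyte markers differed by 0.13 (SE 0.0407), with 20 of 21 higher, among them Slco1a4 (0.28) and Emcn (0.26); adjusted p was 0.00112, and adjusted p = 0.276 with an estimated correlation. Quantile normalization ended this call (0.058, SE 0.0948), as did the filter on SD (0.096). No member of these lists passed over all genes or over its list alone.

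**Figure D2:**
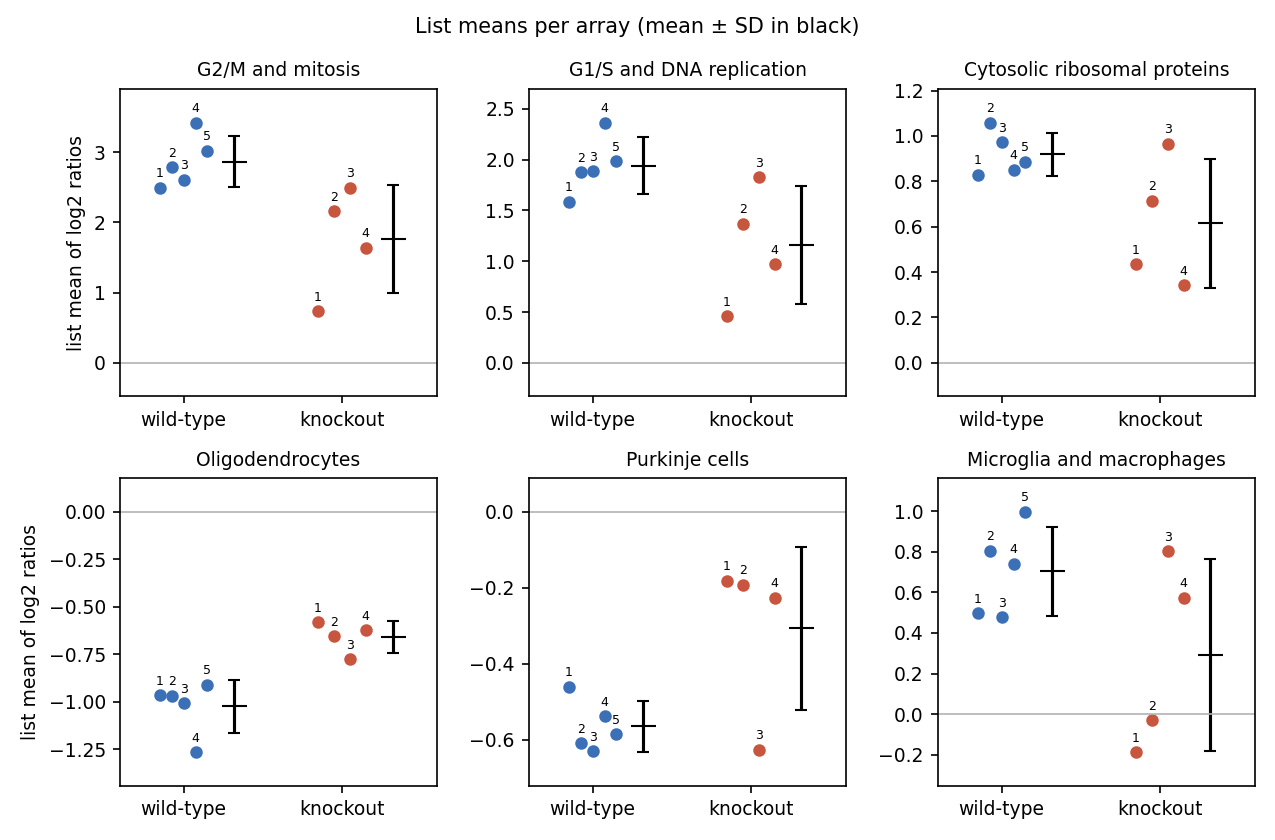
Mean log2 ratio over the reference of the genes in 6 lists (vertical axis), per array, by genotype. Points are arrays with their replicate number and black bars are mean ± SD (n = 5 wild-type, n = 4 knockout). Oligodendrocyte markers separate the genotypes, and knockout 3 lies within the range of the wild-type arrays for the G2/M list, at 2.50.

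Of the lists of immune genes, microglia and macrophages (adjusted p = 0.376 with an estimated correlation), inflammasome (adjusted p = 0.341 with an estimated correlation) and interferon response (adjusted p = 0.557 with an estimated correlation) were called lower in knockout with the preset correlation. Lymphocytes and neutrophils, antigen presentation and complement, and NF-kB targets and cytokines were not called, though some other settings called them. Microglia and macrophage markers differed by -0.41 (SE 0.236), with 23 of 24 lower, among them Aif1 (-0.74), Fcrls (-0.71) and the lysozyme gene Lyz2 (-0.84). Camera gave adjusted p = 1.9e-07, and adjusted p = 0.376 with an estimated correlation, while the exact permutation p was 0.167. Within the array sets these markers differed by -0.76, 0.33 and -0.29, and without knockout 1 by -0.25, with Lyz2 at -0.48. The inflammasome list differed by -0.29 (SE 0.103), with 17 of 26 members lower and 9 higher (adjusted p = 0.024, and adjusted p = 0.341 with an estimated correlation), but it includes Pycard itself, its 1 member past the threshold. Without Pycard it differed by -0.16 and was not called (adjusted p = 0.135). Its call was also lost after quantile normalization (-0.26) and without knockout 1 (-0.22), knockout 2 (-0.26), wild-type 2 (-0.27) or wild-type 4 (-0.28), and by array set the difference was -0.38, -0.061 and -0.27. Casp4 (-0.87) was lower and the sensor gene Nlrp6 (0.64) higher without passing. Interferon response genes differed by -0.25 (SE 0.239; Irf1 -0.39, Ifit2 -0.93, Cxcl10 -1.35), with adjusted p = 0.00274, adjusted p = 0.557 with an estimated correlation, and adjusted p = 0.432 with the replicate block. Within the array sets they differed by -0.11, 0.29 and -0.67, and the call was lost without wild-type 5 (-0.10), without knockout 2 (-0.16) and after quantile normalization (-0.12). Apoptosis genes differed by -0.18 (SE 0.102), with adjusted p = 0.0212, adjusted p = 0.463 with an estimated correlation, and adjusted p = 0.0755 with the replicate block. This call too was lost after quantile normalization (-0.11), and without knockout 1 (-0.12), knockout 2 (-0.18), wild-type 4 (-0.13) or wild-type 5 (-0.15). It was lost as well within the letter-titled arrays (-0.091), by single features (-0.072), with array weights, with the name-style block, with the array-set block and in the set of 4 (-0.15 in each of the last 4), and by array set the difference was -0.15, 0.024 and -0.29. The leading members were Birc5 (-1.26), which is also a mitotic gene, Casp8 (-0.43) and Pmaip1 (-0.45). Without knockout 1 Birc5 was at -0.79 and Pmaip1 at -0.22, and without wild-type 4 Pmaip1 was at -0.19.

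Both lists of energy metabolism were called higher in knockout by small differences, and both calls were lost in several settings. The oxidative phosphorylation list differed by 0.11 (SE 0.0848), with 28 of 32 higher, among them Sdhb (0.22), Ndufs1 (0.21) and Cox6c (0.26), and Ndufs4 at -0.25. Its adjusted p was 0.00115, and adjusted p = 0.472 with an estimated correlation. The difference was 0.054 without knockout 1 (call lost) and 0.16 without knockout 3. Its call was also lost within the letter-titled arrays (0.055) and with the filter on SD (0.13, adjusted p = 0.17), and the array sets gave 0.087, -0.010 and 0.16. Without knockout 4 Sdhb was at 0.145, Cox6c at 0.42 and Ndufs4 at 0.077. Ndufs4 was at -0.39 without knockout 2 and -0.40 without knockout 3, and Cox6c at 0.16 without knockout 1 and 0.17 without wild-type 5. Glycolysis genes differed by 0.09 (SE 0.0574), with Ldhb (0.24) and Aldoc (0.42) higher and the hexokinase gene Hk2 lower (-0.78). The adjusted p was 0.0198, and adjusted p = 0.376 with an estimated correlation. The glycolysis call was lost without wild-type 4 (0.046) or knockout 4 (0.077), after quantile normalization (0.030, SE 0.0438), within the letter-titled arrays (0.0097), with the filter on SD (0.047), with array weights (0.038) and in the set of 4 (0.024). Glycolysis genes differed by 0.024, -0.018 and 0.23 within the array sets, and Aldoc was at 0.27 without knockout 4.

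The other 17 lists were not called in the fit of all 9 arrays as deposited, without block or weights and with features averaged per gene. Lymphocytes and neutrophils differed by -0.20 (adjusted p = 0.0565, and adjusted p = 0.0425 with the replicate block), and extracellular matrix and proteases by 0.05 (adjusted p = 0.387, and adjusted p = 0.0415 with the replicate block). The p53 targets differed by -0.04 (adjusted p = 0.9), with Phlda3 at 0.33, Eda2r at -0.66 and Mdm2 at -0.47 (-0.13 without wild-type 4). Cyclin-dependent kinase inhibitors differed by -0.21 (adjusted p = 0.124; Cdkn2c -0.51, Cdkn2a -0.41, Cdkn1b -0.41, the features of the last 2 genes differing in sign). Cdkn2a was at -0.27 without knockout 1 and -0.26 without wild-type 3. Cdkn1b ran from -0.80 (without knockout 4) to -0.12 (without wild-type 5), with -0.66 without wild-type 3, -0.25 without knockout 3 and -0.20 without knockout 1. Differences were -0.10 for antigen presentation and complement (adjusted p = 0.139), -0.23 for erythroid cells, -0.04 for Wnt and Notch signaling, 0.07 for meninges and fibroblasts and -0.05 for heat shock and unfolded protein genes. They were 0.04 for hypoxia, -0.11 for NF-kB targets and cytokines (adjusted p = 0.414), -0.12 for oligodendrocyte precursors, 0.02 for TGF-beta and BMP signaling and -0.04 for immediate early genes. Choroid plexus and ependyma markers differed by -0.12 (-1.74, 1.99 and 0.91 within the array sets), the genes next to Pycard by -0.02 and sex-linked genes by 0.16. In these last 3 lists and in the p53 list the median, the mean and the test differ in sign. Leaving out 1 array called some of these lists. Without knockout 3 these were antigen presentation (-0.24) and NF-kB targets (-0.25), without knockout 4 the kinase inhibitors (-0.32), erythroid cells (-0.47) and lymphocytes (-0.20), without wild-type 2 erythroid cells (-0.39) and lymphocytes (-0.29), and without wild-type 5 lymphocytes (-0.23). The differences nearest 0 were -0.035 for antigen presentation, -0.030 for NF-kB targets and -0.10 for kinase inhibitors (each without knockout 1), -0.050 for erythroid cells (without knockout 2) and -0.072 for lymphocytes (without wild-type 4). In the set of 4, antigen presentation (-0.20), NF-kB targets (-0.38), kinase inhibitors (-0.30) and choroid plexus (-1.74) were called. Array weights called antigen presentation (-0.19), NF-kB targets (-0.32), kinase inhibitors (-0.24), immediate early genes (-0.22) and choroid plexus (-1.33). Single features called antigen presentation (-0.11), extracellular matrix (0.095), oligodendrocyte precursors (-0.37) and immediate early genes (-0.19). Lymphocytes were called with exact zeros as missing (-0.25) and heat shock genes after quantile normalization (-0.11). Within the number-titled arrays, with knockout 4 as the only knockout array, sex-linked genes differed by -0.38 and choroid plexus by 0.91. In all, camera called 18 of 35 lists, 10 lower and 8 higher, against 8 lower and 4 higher after quantile normalization. With an estimated correlation 0 were called (6 with an unadjusted p under 0.05), fry called 0, and the exact permutation test called 0 after adjustment (6 with an unadjusted exact p under 0.05). The exact test can give no p below 0.00794, so 1 list alone cannot pass adjustment over 35 lists. Its 0 therefore says little.

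For knockout against wild-type, other settings also ended these calls. The inflammasome call was lost within letter-titled arrays and with the array-set block (-0.27 in each). Within the number-titled arrays, with knockout 4 as the only knockout array, the inflammasome list differed by -0.27 and the endothelial list by 0.13. In the set of 4 the calls of granule neuron maturation (0.11), interneurons (0.20) and interferon response (-0.11) were lost. The astrocyte call was lost by single features (-0.0087), in the set of 4 (-0.035), with array weights (0.0045), with the name-style and array-set blocks (0.12 in each) and with the Xist covariate (0.14), and the interferon call within letter-titled arrays (0.021). Values that moved by over 1.5 times within the number-titled arrays, with knockout 4 as the only knockout array, were G1/S (-1.21), ribosomal proteins (-0.53) and DNA damage (-0.80). So did granule neuron maturation (0.55), interneurons (0.29), glycolysis (0.23) and apoptosis (-0.29). Calls kept with a value moved by over 1.5 times were DNA damage within letter-titled arrays (-0.27), microglia with array weights (-0.67) and apoptosis with the filter on SD (-0.28).

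**Figure D3:**
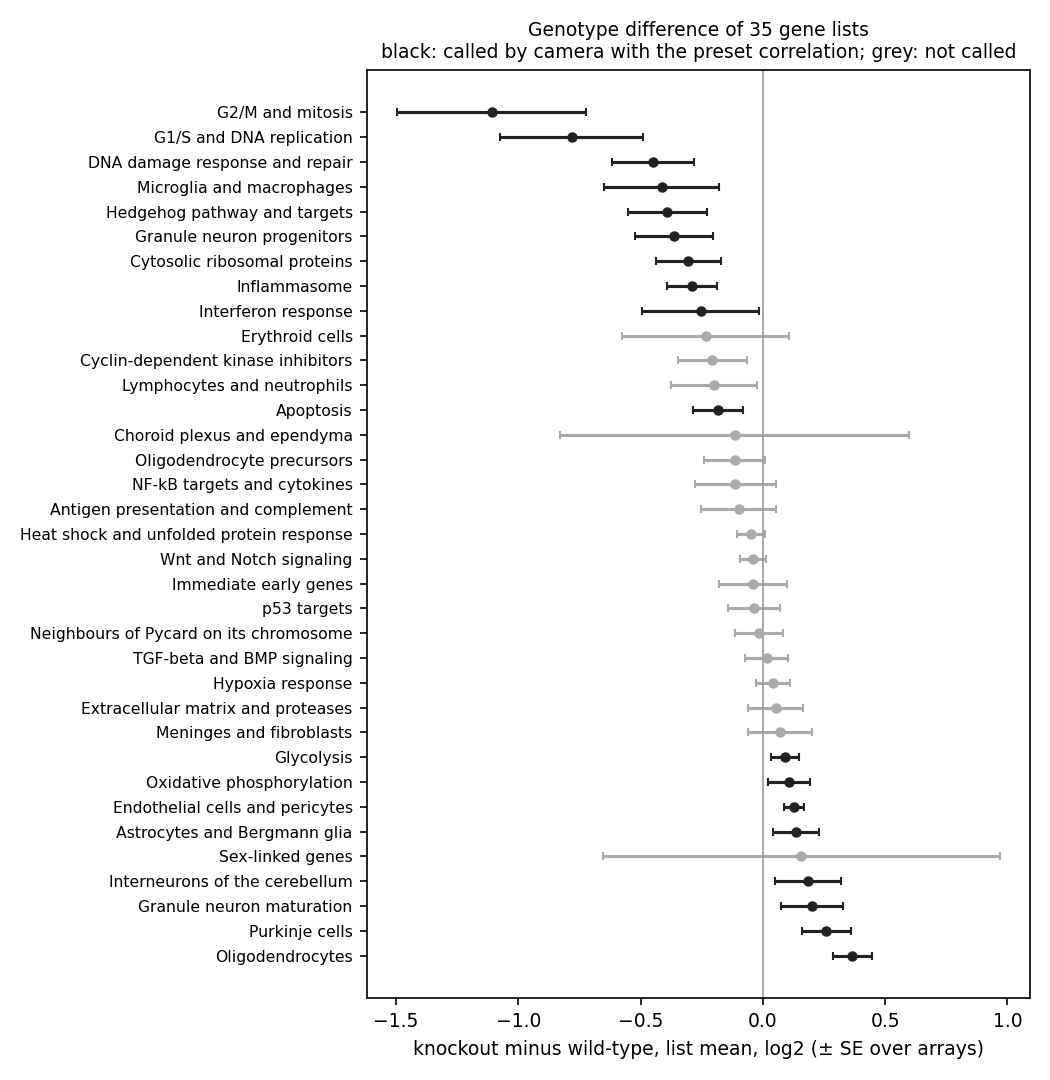
Knockout minus wild-type difference of the list mean on the log2 scale (horizontal axis) for 35 gene lists, with SE over the 9 arrays as bars. Black marks the 18 lists called by camera with the preset correlation, from -1.11 for G2/M and mitosis to 0.37 for oligodendrocytes, and grey the others.

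Against the younger wild-type pool, camera with the preset correlation called lists of dividing and progenitor cells higher in the SmoA1 cerebellum with intact Pycard, and lists of differentiated cells lower. With an estimated correlation 2 of these calls held, oligodendrocytes and endothelial cells, while G2/M had adjusted p = 0.155, progenitors adjusted p = 0.216 and granule neuron maturation adjusted p = 0.282. Mki67, a marker of proliferating cells, stood at 3.78 on the log2 scale (13.7-fold, limma adjusted p = 0.00029, n = 5). The Hedgehog target Mycn stood at 2.94, the granule progenitor factor Atoh1 at 2.85, Gli1 at 0.71 (limma adjusted p = 0.0131) and Ccnd1 at 0.88 (limma adjusted p = 0.00218). Ptch1 did not pass (0.04, limma adjusted p = 0.849), and its 13 features disagree in sign. Myelin gene Mbp was at -0.80 (limma adjusted p = 0.00113), with 12 features from -1.29 to 1.32, and Gabra6, of mature granule neurons, at -0.73 (limma adjusted p = 0.00928). Past the threshold with a mean of at least 1 either way were 1689 values, 1143 higher and 546 lower, of which 710 and 251 belong to named genes. The highest with all arrays above 0 were Foxa2 (6.12), Aurkb (4.77), Cxcl10 (4.40), Birc5 (4.20), Esco2 (4.19), Pbk (4.06), Tox3 (4.01) and Uhrf1 (4.01). The lowest were Wif1 (-3.01), which encodes a secreted Wnt inhibitor, Wnt10b (-2.58), Plac9a (-2.27), Meig1 (-2.16), Gchfr (-2.03), Gdf10 (-1.97), Ccl19 (-1.92) and Tmem212 (-1.90). Of these, Wnt10b was at -1.71 without wild-type 4, Meig1 lost its call without wild-type 4 (-1.90), and Tmem212 lost its call without wild-type 3 (-1.46) or wild-type 4 (-1.58). Transgene, age, dye and the single pool cannot be told apart here, and the spread of the pooled animals is not in the test. Within the 3 number-titled arrays limma called 0 values.

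Camera called 24 lists against the reference, 11 higher and 13 lower. Fry called 22 of the 24, but it tests a list against 0, where camera tests it against the other genes. The count by fry is therefore no check on the calls by camera. With an estimated correlation camera called 2. These are oligodendrocytes (-1.02) and endothelial cells and pericytes (-0.43), both with adjusted p = 0.0453 with an estimated correlation. For G2/M and mitosis (2.87) 31 of 32 members passed as higher with a mean of at least 1, and for G1/S and DNA replication (1.94) 25 of 32, with adjusted p = 0.155 with an estimated correlation for each list. Ribosomal proteins stood at 0.92, with 12 of 35 members passing as higher with a mean of at least 1 (35 with no minimum) and adjusted p = 0.155 with an estimated correlation. Also higher were granule neuron progenitors at 0.92 and the inflammasome at 0.38 (adjusted p = 0.216 with an estimated correlation for each), and DNA damage genes at 0.80 (adjusted p = 0.215 with an estimated correlation). The Hedgehog list at 0.79, microglia at 0.70, interferon response at 0.70, apoptosis at 0.40 and lymphocytes and neutrophils at 0.39 were higher, with adjusted p = 0.319 with an estimated correlation for each. Lower were interneurons (-0.63), Purkinje cells (-0.56), glycolysis (-0.30), heat shock genes (-0.26) and hypoxia genes (-0.26), with adjusted p = 0.155 with an estimated correlation for each. Astrocytes at -0.47 and extracellular matrix at -0.43 had adjusted p = 0.213 with an estimated correlation, and granule neuron maturation at -0.41, with 0 of 20 members passing as lower with a mean of at least 1 either way (11 with no minimum), had adjusted p = 0.282 with an estimated correlation. Meninges and fibroblasts at -0.34 had adjusted p = 0.319 with an estimated correlation. Choroid plexus and ependyma at -0.87 and oxidative phosphorylation at -0.11 had adjusted p = 0.512 with an estimated correlation. The choroid plexus call was lost with the replicate number as a random block (adjusted p = 0.0692), without wild-type 3 (-0.54) and without wild-type 4 (-0.63). Leaving out wild-type 3 (-0.10) or wild-type 5 (-0.085) ended the oxidative phosphorylation call. Without wild-type 4 the apoptosis (0.34) and lymphocyte (0.27) calls were lost.

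Other settings ended further list calls against the reference. Within the letter-titled arrays these were Hedgehog (0.67), oxidative phosphorylation (-0.045), apoptosis (0.29) and lymphocytes and neutrophils (0.26), and within the number-titled arrays meninges (-0.31), heat shock (-0.22) and hypoxia (-0.21). In the set of 4 they were Hedgehog (0.58), interferon response (0.39), inflammasome (0.32), apoptosis (0.27), lymphocytes and neutrophils (0.20), choroid plexus (-0.10) and oxidative phosphorylation (0.011). With array weights the calls of choroid plexus (-0.19), oxidative phosphorylation (-0.028), apoptosis (0.32) and lymphocytes and neutrophils (0.20) were lost, and by single features those of choroid plexus (-0.21) and apoptosis (0.092). The filter on SD ended those of glycolysis (-0.18), oxidative phosphorylation (-0.13), meninges (-0.30), heat shock (-0.31) and hypoxia (-0.22). Calls kept with a value moved by over 1.5 times were DNA damage (0.51), astrocytes (-0.20), lymphocytes and neutrophils (0.22) and meninges (-0.58) by single features. Others were interferon response within letter-titled (0.43) and number-titled arrays (1.11), and lymphocytes and neutrophils (0.60) and oxidative phosphorylation (-0.22) within number-titled arrays.

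Sex-linked transcripts divided the arrays across genotypes. Eif2s3y, on the Y chromosome, lay between -0.17 and 0.36 on wild-type 1 and 2 and knockout 1 and 2, and between -9.78 and -6.39 on the other 5 arrays, 3 wild-type and 2 knockout. Kdm5d and Uty divided the arrays likewise, with Kdm5d at -0.15 to 0.08 against -4.57 to -3.27. Xist, expressed from the inactive X chromosome, ranged from -0.09 to 0.40 on the 4 arrays and from -0.05 to 1.58 on the 5. The genotypes are divided 2 to 2 and 3 to 2 in this respect.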

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

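The tests of array sets, of sex, of position on chromosome 7 and of Xist were chosen only after the results they bear on had been seen.

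Dividing the 9 arrays in other ways tested both counts for knockout against wild-type. Of 100 splits drawn from 126, 2 gave at least the 5 values of the real split, the real one included, but most of these splits ignore the pairing by number. The other one gave 7 and set wild-type 1 and 2 and knockout 1 and 2 against the rest, which is the array set with Y-linked signal; with the array sets as a block 3 values were called, and 0 within that set. For gene lists, 6 of 100 splits gave at least the 18 of the real split, and the highest other gave 22, so chance cannot be excluded for the number of lists. The splits that part all 4 numbered pairs, as the real one does, are 16, too few for a share under 0.05; the real one gave 5 values and the highest other 0. For lists 2 of these 16 gave as many as the real split, with the highest other at 19. With the replicate number as a block limma called 0 values (1868 with an unadjusted p under 0.05).

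The lower G2/M and mitosis list in knockout was -1.11 (SE 0.386) as deposited. A shift of whole array sets, common to both genotypes, could add little to this difference, because each set holds both in similar numbers. With the sets as a block the difference was -1.06 (SE 0.407), and -1.07 (SE 0.419) with the replicate number as a block. The same near balance means that these blocks could hardly have moved the difference, so they are no independent test. The sets were formed after each genotype's mean was subtracted, so a batch that follows genotype would not show in them. Within the sets the difference was -1.19, -0.11 and -1.58, which the array-set block does not model. Sex as far as Eif2s3y marks it divides both genotypes almost alike, so an effect common to them could also add little. The Eif2s3y ratio as a covariate repeats the array-set block, since 99.3% of the Eif2s3y variance lies between the sets. With this covariate the difference was -1.06 (SE 0.379), which is no independent test either. Sex not marked by Eif2s3y was not tested. The narrower spread of ratios on the knockout arrays stays open, because after quantile normalization the difference was -0.74 (SE 0.391), neither near 0 nor clearly beyond the bound set for it. As a hypothesis, a lower share of dividing progenitor cells in the knockout may underlie the pattern. It was not tested, and progenitor markers differed by -0.36 (camera adjusted p = 0.341 with an estimated correlation). Chance stays open beside it.

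Slx1b and Gdpd3 lie 66 and 63 measured genes from Pycard on chromosome 7, in the gene order of assembly GRCm38.p6. The probability that both fall within 200 measured genes of Pycard by position alone is 0.00044. That window was chosen after the 2 genes had been seen, so the value describes their closeness and is no independent test of chance position. Flanking DNA of another strain, carried along with the targeted allele, is a candidate explanation. Leaving out Pycard, Slx1b and Gdpd3, 9 of 398 genes in that window had p under 0.01 against 0.847% elsewhere, an odds ratio of 2.71 (95% interval 1.21 to 5.32, Fisher's exact p = 0.00863), with odds ratios of 4.80 (Fisher's exact p = 0.0117), 4.28 (Fisher's exact p = 0.00185) and 1.94 (Fisher's exact p = 0.0708) in windows of 50, 100 and 400. The 9 include Armc5 and Nkx6-2, and also Plk1 and Kif22, which are cell division genes. Without cell cycle genes the odds ratio was 2.15 (Fisher's exact p = 0.0529), so the excess rests partly on cell cycle genes. An effect of lost ASC on the genes in the window was not tested.

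Eif2s3y, Kdm5d and Uty part 4 arrays, near the pool, from 5 far below it. RNA of males alone on the 4 arrays, against a pool of both sexes, is argued against by their mean Xist ratio of 0.15 (SD 0.202), since males lack Xist and would lie far below the pool. Samples and pool that both mix sexes in like shares, and females alone or a different pool or labelling on the other 5 arrays, stay open and were not tested. On those 5 arrays Xist was at 0.94 to 1.58, except for -0.05 on wild-type 4. Both genotypes lie on each side of this division.

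Of 286 groups of arrays examined, 15 have 1 array far from the others, where about 14.3 would by chance. Knockout 3 stood apart from the other knockout arrays in 7 of them. Its list mean was -0.63 for Purkinje cells (others -0.23 to -0.18), -0.80 for interneurons (others -0.36 to -0.29) and 0.64 for antigen presentation and complement (others 0.01 to 0.12). On the same array Gdpd3 was 1.93 (others 0.96 to 1.02), Gdf10 -2.23 (others -0.90 to -0.73), Fabp7 1.17 (others -0.07 to 0.04) and Ccl19 -0.73 (others -2.19 to -2.02). Wild-type 4 was apart in oligodendrocyte markers at -1.26 (others -1.01 to -0.91), Phlda3 at -0.68 (others -0.89 to -0.84), Fancd2 at 3.75 (others 1.06 to 1.75) and Wnt10b at -6.07 (others -2.24 to -1.38). Wild-type 3 was apart in Mfap5 at -1.54 (others -1.01 to -0.80). Wild-type 5 was apart in Slc6a5 at -1.50 (others -1.03 to -0.85) and Uhrf1 at 3.33 (others 4.03 to 4.28). Knockout 4 was apart in Sdhb at 0.32 (others -0.001 to 0.049).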

How the results depend on the processing

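The array-set block, the Eif2s3y covariate, exact zeros as missing, named genes alone and the set of 4 arrays alone were chosen after seeing the data. Unless said otherwise the cause of a change was not tested. No missing cell exists, so a filter on complete values changes nothing. Median centring, the name-style block, the filter on SD, array weights, the trended prior, the Xist and Eif2s3y covariates and exact zeros as missing kept all 5 main results within 1.5 times or on the same side of the threshold, each where it was run. With no signal intensities, what background limits was not examined.

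Pycard (-3.47) lost its call with the replicate block (-3.41), within the letter-titled arrays (-3.18), within the number-titled ones (-4.13), after quantile normalization (-3.86), in its weaker feature (-2.32), with the array-set block (-3.47) and in the set of 4 (-3.67); its difference was -3.78 to -3.33 with 1 array left out. The count of 5 changed values became 0 with the replicate block, 0 within letter-titled, 0 within number-titled and 0 in the set of 4 arrays, where fewer arrays enter. It was 3 after quantile normalization, 3 with the array-set block and 3 with named genes alone, where 2 unnamed features are left out. It was 1 by the unmoderated two-sample test and 239 at an unadjusted p under 0.01. With 1 array left out it was 1 without wild-type 1, 2 or 5 or knockout 1 or 2, and 2 without wild-type 4 or knockout 4. It was 3 without knockout 3 and 6 without wild-type 3. The 18 lists became 11 within letter-titled arrays, 0 with an estimated correlation and 0 by fry, and 13 to 19 with 1 array left out. The replicate block changed the calls of Pycard, Slx1b, Gdpd3, both unnamed features, interferon, apoptosis, lymphocyte and matrix lists, and of choroid plexus against the reference, and no other call. The 1689 values away from the reference became 0 within number-titled arrays, 2628 by single features, 7650 with no minimum and 995 with named genes alone, and 1448 to 1789 with 1 array left out; the 24 lists became 2 with an estimated correlation, and fry called 22 of them, without oxidative phosphorylation and choroid plexus. After quantile normalization 11 of the 18 stayed called, and 17 without Pycard and its neighbours. Under each setting run, all 18 called lists kept their direction except interferon within letter-titled arrays (0.021) and astrocytes by single features (-0.0087) and in the set of 4 (-0.035). Wild-type 3 against knockout 3 alone was not run as a setting. Between these arrays microglia (0.33), interferon (0.29) and granule neuron maturation (-0.14) had the other sign. So did progenitors, DNA damage, apoptosis, glycolysis and oxidative phosphorylation, each nearer 0.

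Signs turned in lists and genes near 0 or of wide spread. Sex-linked genes (0.16) were -0.061 with the replicate block, -0.10 with the name-style and array-set blocks, -0.38 within number-titled arrays, -0.064 with the Eif2s3y covariate and -0.23 to 0.65 with 1 array left out. Choroid plexus (-0.12, not called) was 0.068 with the replicate block, -0.68 after quantile normalization and -0.45 to 0.21 with 1 left out. It was called in the set of 4 (-1.74, camera adjusted p = 5.9e-06) and with array weights (-1.33, camera adjusted p = 0.000118). Within the number-titled arrays, with knockout 4 as the only knockout array, it was 0.91. The p53 targets (-0.04) were 0.0018 with the replicate block, 0.00069 with the name-style and array-set blocks, 0.045 within letter-titled arrays, 0.034 in the set of 4 and -0.10 to 0.016 with 1 left out. Erythroid genes (-0.23) were 0.049 within number-titled arrays and 0.016 in the set of 4, neighbours of Pycard 0.041 within number-titled arrays and -0.074 to 0.036 with 1 left out. After quantile normalization, with array weights and in the set of 4, meninges were -0.022, -0.054 and -0.040 (-0.015 to 0.14 with 1 left out) and extracellular matrix -0.069, -0.036 and -0.081 (-0.024 to 0.11). Immediate early genes were 0.032 after quantile normalization (-0.11 to 0.040). TGF-beta and BMP genes were -0.0051 with the SD filter, -0.030 with weights and -0.028 in the set of 4 (-0.028 to 0.072). Wnt and Notch genes were 0.023 with weights and 0.0065 in the set of 4. Ndufs4 was 0.041 within letter-titled arrays and 0.095 by a single feature (-0.40 to 0.077 with 1 left out), Cdkn2a 0.022 within number-titled arrays and 0.0066 by a single feature, Cdkn1b 0.023 by a single feature and Mdm2 0.058 in the set of 4. Against the reference, Ptch1 was -0.19 within letter-titled arrays, -0.17 with weights and -0.24 in the set of 4 (-0.071 to 0.13 with 1 left out), and oxidative phosphorylation 0.011 in the set of 4.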

Other observations

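The test of a pull toward the reference was chosen before its result was seen.

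Choroid plexus transcripts varied between arrays far more than between genotypes. Ttr, the carrier of thyroid hormone made by the choroid plexus, was at -4.63 and -4.52 on knockout 1 and 2, at -4.48 on wild-type 3 and at -3.27 on wild-type 4. On the others it was -1.06 (wild-type 1), 1.08 (wild-type 2), 0.11 (knockout 3), 0.42 (knockout 4) and 0.19 (wild-type 5). Sostdc1 ran from -5.53 on wild-type 3 to 0.64 on wild-type 2, Aqp1 from -3.02 to 0.43 and Folr1 from -2.01 to 0.53. The list mean lay between -2.19 and 0.44, with both genotypes at the low and the high end. Cilia gene Tmem212 was below 0 on all 9 arrays, from -3.67 to -0.60.

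Several lists that stood away from the reference in wild-type arrays were nearer to it in knockout. G2/M genes went from 2.87 to 1.76 and oligodendrocyte genes from -1.02 to -0.66. A hypothesis was that values of the knockout lie nearer the reference across the genome. With 2 wild-type arrays giving the reference ratio and the other 3 the genotype difference, the correlation across genes, which are not independent replicates, was between -0.374 and -0.132 over 10 divisions. A wild-type array in place of the knockout gave correlations between -0.219 and 0.207 with a median of -0.00826. All 10 divisions of the knockout lie below that median, but the ranges overlap, so a pull across the genome beyond that of single wild-type arrays was not shown. The knockout enters as a mean of 4 arrays and each placement as 1 array, which spreads the placements more. The overlap therefore cannot exclude such a pull.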
